A study of Drosophila melanogaster with 4 samples.

How the data were processed

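ChIP-seq with an antibody against GFP was done on 4 biological replicates of whole white prepupae, males and females together, that stably expressed Eip78C with GFP at its C-terminus. Per the labels, chromatin was sheared by sonication and the size range was 200 to 800 (unit not stated). All 4 samples form 1 group, and replicate numbers are those of the labels. Nothing here pairs samples.

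Peak lists were deposited on dm6 and dm3. Per the file headers deposited with the samples, each replicate's list was called by the authors on that replicate's alignment with a control alignment, and a further list was called on the 4 alignments pooled. Per the same source, the joint list is a set thresholded by irreproducible discovery rate (IDR), which keeps peaks whose ranks repeat between replicates. It was derived from the lists of replicates 2, 3 and 4 and from the pooled list, and the list of replicate 1 was not among its sources. The aligner, the peak caller, the IDR threshold and their versions are not given in the sources used here. The deposited lists give each peak a signal score made by the authors, on a scale that is not stated, and −log10 of a q-value. All 8282 optimal peaks sat at the ceiling of the −log10 q column (4.26 in the pooled list), so peaks were ranked by the score. The score is the authors' and was used only to rank and describe peaks within 1 list. In 5 of 5 compared columns (arm, start, end, summit and score) the optimal set equalled the 8282 highest-scoring peaks of the pooled list. The replicate lists are relaxed lists of exactly 30000 peaks that include background, so their 8282 strongest peaks were used wherever replicates were compared. Lists of a fixed number of peaks show no difference in the number of bound sites.

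Coordinates were used on dm6 only, and dm3 lists only for counts. No peak of the dm6 lists ended beyond an arm of the dm6 reference. Positions are 1-based and each peak stands at its summit. Genes came from the dm6 Ensembl annotation, with 13968 protein-coding genes on the arms 2L, 2R, 3L, 3R, 4, X and Y, and transposable elements were left out. Shares of summits within 1 kb of a TSS and in 7 annotation classes were compared with the share of bases, weighted by the peaks per arm, by two-sided exact binomial tests. Classes were assigned in the order promoter (within 1 kb of a TSS), 5′ UTR, 3′ UTR, coding exon, other exon, intron and intergenic. The 22 gene lists were tested with two-sided Fisher's exact tests against all other protein-coding genes, and peak strength with a permutation test of the mean rank (100000 resamples, lists with at least 5 peaks). The 16 motifs were counted on either strand in 200 bp centred on each summit and in 200 bp centred 500 bp to its right, and compared with the two-sided exact McNemar (binomial) test. Up to 100 letter-scrambled versions of each consensus were counted in the same windows. Adjusted p is by Benjamini-Hochberg within each family, with a threshold of 0.05. Genes and summits are not independent replicates, so these tests describe the peak set, and the spread over 4 replicates is the biological error.

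Gene lists, motifs, tests, alternatives and the rule for named genes were fixed before the data were examined. Symbols were matched to the annotation by name and synonym. The gene stl of the disc list had been missed because of a capital letter, and this was corrected after the results were seen: without it the disc list had 9 of 19 members with a summit and an adjusted p of 0.0431, and with it 9 of 20 and 0.0511 (Fisher's exact test). The rule names Eip78C, then every member of the ecdysone response and nuclear receptor lists with its strongest optimal peak within 1 kb of a TSS, or as having none. It then names the genes with the TSS nearest to the 10 strongest peaks, and up to 4 members of each other list with the strongest peak within 1 kb of a TSS. Some members that this rule names are not reported here. Other genes, such as fat body storage genes without a peak and members with summits inside the gene, were named after their values were seen. The share overlapped by chance is the share of positions at which an interval of the median optimal width meets a replicate peak. Intervals at 95% are exact (Clopper-Pearson) and, like the limits for a count of 0 (3 counts of the total), cover counting error only.

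The TSS share, the gene-list test, the motif test, the peak-strength test and peak overlap were tested on simulated data. Other tests, including the comparisons with matched gene lists, with scrambled motifs and of chromosome arms, were not tested in this way. With summits planted near TSSs at known shares, 19 of 20 shares of 8282 summits fell within the exact interval, and 0 of 10 random sets were called. Over 13968 genes, 96 of 100 lists with planted summits and 3 of 340 random lists were called. All 4 motifs planted in 2% of 8282 windows and 0 of 16 motifs at random positions were called, there at p under 0.05 divided by the number of motifs. Random positions lack the AT-rich centre of the real summits, and random lists lack the gene length and TSS number of the real lists. These simulations therefore do not measure false calls that come from base composition or gene length. In the strength test 20 of 20 lists drawn from stronger peaks and 2 of 20 random lists were called. Overlap found 100% of shared simulated peaks and 5.39% of unrelated ones. Calculations used Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1, and figures matplotlib 3.10.9.

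Alternatives were a stricter set, peaks met by all 4 replicates, other overlap rules, other TSS and motif windows, other ways to assign peaks to genes, matched lists, and leaving out each replicate. For a left-out replicate the value is the mean over the remaining replicates, with the largest adjusted p among them. The remaining replicates' own lists were used, and no peak set was rebuilt without a replicate. A call lost in this way failed in a replicate that was kept. The weaker pooled peaks as background, and the ranks of named peaks without each replicate, were added after seeing the data. Signal tracks were not analysed here.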

Results

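Chromatin recovered with tagged Eip78C was mapped in whole Drosophila melanogaster of both sexes at the white prepupa stage. Eip78C is a nuclear receptor of the Rev-erb type whose gene is induced by the moulting hormone ecdysone. White prepupae are animals that have just stopped crawling and begun to form the puparium. The animals carried Eip78C fused at its C-terminus to green fluorescent protein, and an antibody against that tag was used for chromatin immunoprecipitation and sequencing (ChIP-seq) of 4 biological replicates. All 4 form 1 group. No untagged or input sample was among the samples analysed here, so no background was measured in the same way. The deposited lists give peaks and no read counts, so the sequencing depth behind each list is unknown. Each replicate list and the list called on the pooled replicates held 30000 peaks on each genome build. The joint, thresholded list, called the optimal set below, held 8282 peaks on dm6. These were 8164 different intervals with a median width of 372 bp, and they merged into 7880 regions.

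The 4 replicates carried largely the same sites. The optimal set was compared with the 8282 strongest peaks of each replicate, counting any overlap of at least 1 bp. On average 83.6% ± 1.21 (SD, n = 4) of the optimal peaks were met by a replicate, where 4.17% would be met by chance. High overlap was built in, because the optimal set equalled the strongest peaks called on these 4 replicates pooled. The chance value places intervals evenly over all arms, so it is a low bar. Replicate 1 was not used to threshold the optimal set, although its reads were in the pooled list. It met 82.2% of the set, and the other 3 replicates met between 83.3% and 85.1%. All 4 replicates met 5062 of the optimal peaks, and 32 peaks were met by none of them. Between pairs of replicates 77.1% ± 2.18 (SD over 6 pairs) of the strongest peaks were shared. The signals of shared peaks were correlated with Spearman's rho between 0.712 and 0.795. These correlations are across peaks, which are not independent replicates.

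A peak inside the gene of the tagged receptor itself was among the strongest of the set. Without an untagged control, whether the receptor binds there is not settled. Eip78C (FBgn0004865) lies on arm 3L from 21226609 to 21266503, on the plus strand, and 11 optimal peaks had their summits inside it. The strongest, at 3L from 21253526 to 21254170 with its summit at 21253899, lay in an intron and ranked 5 of 8282, with a signal of 3654. It ranked 4, 8, 5 and 4 in replicates 1 to 4 (mean 5.25 ± 1.89, SD, n = 4). The next peaks inside the gene, with summits at 21251507 and 21253167, were also intronic and ranked 775 and 940, with signals of 617 and 556. Peaks at the annotated promoters were much weaker. The strongest peak within 1 kb of an Eip78C transcription start site (TSS) had its summit 32 bp downstream of the start, in the 5′ UTR, and ranked 5001, with a signal of 163 and a mean replicate rank of 6893 ± 2883 (SD, n = 4). The labels do not say where the tagged copy was inserted.

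**Figure D1:**
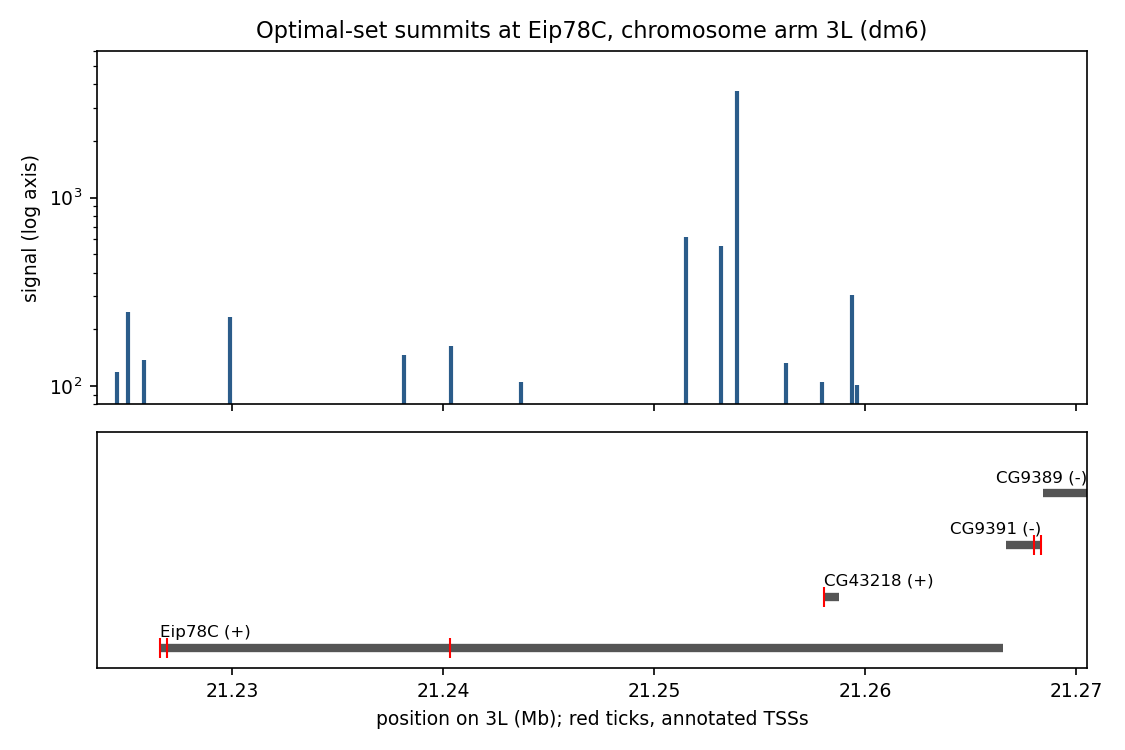
Optimal-set summits across the Eip78C gene, with position on arm 3L in dm6 (Mb) on the horizontal axis and the authors' signal on a log vertical axis. Vertical lines are summits and grey bars in the lower panel are genes, with red ticks at annotated TSSs; the intronic summit at a signal of 3654 stands above the next, at 617.

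Genes of the ecdysone response carried peaks at their promoters more often than other genes. A summit lay within 1 kb of a TSS for 14 of 25 listed ecdysone response genes (56.0%), against 22.0% of the other 13943 protein-coding genes (odds ratio 4.52; p = 0.000226, adjusted p = 0.00147, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 22 lists). The odds ratios of the replicates' own lists averaged 5.69 to 8.05 over sets of 3 replicates. In the optimal set the odds ratio was 9.73 with summits in the gene body or 2 kb upstream and 11.6 with summits given to the nearest TSS. The gene-body and nearest-TSS rules reach further at genes that are long or far from others, and no matched lists were run under them. The mean share over the 4 replicates was 68.0% ± 8.64 (SD), against 24.4% ± 2.44 for all protein-coding genes. These genes are long and have many TSSs. Against 10000 lists matched on gene length and number of TSSs, which averaged 47.1%, the share did not stand out (ratio 1.19, adjusted p = 0.685, permutation test). The strongest promoter peaks were at E23, an ABC transporter gene (rank 217, mean replicate rank 250 ± 138, SD, n = 4; summit at 2L 3355053, 224 bp upstream), and at Eip75B, the other Rev-erb type receptor gene of the fly (rank 286, mean 323 ± 89.3, n = 4; summit at 3L 17999777, in a 5′ UTR). Eip63F-1 followed at rank 1103, Blimp-1, a repressor gene, at 1316 and Hr3 at 1484. The early gene Eip74EF (rank 2413), Eip63E (2494) and usp (2512), which encodes the partner of the ecdysone receptor, had peaks of middle rank. So did vri (3590), the coactivator gene tai (3742), Eip93F (3743) and EcR, the ecdysone receptor gene (4524). The competence factor gene ftz-f1 had the weakest, at rank 7582, which was among the 8282 strongest peaks of only 1 replicate.

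The remaining 11 members had no summit within 1 kb of a TSS, and several of them had summits elsewhere in the gene. Counts inside a gene grow with its length, and those given here were not compared with what length alone gives. Large arms averaged 55.6 (2R) to 67.0 (X) peaks per Mb, so a long gene can hold summits without being preferred. Hr4 held 11 optimal summits inside the gene, the Broad-Complex gene br held 3, Hr38 and Hr39 held 2 each, and Kr-h1 and crol held 1 each. Cth, Cyp18a1, Hr78, MsrA and rig had none. Eip75B held 17 summits inside the gene, Eip63E and tai 13 each, EcR 11, vri 10, Eip74EF 9, Hr3 and ftz-f1 8 each, E23 6 and Eip93F 4.

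Nuclear receptor genes as a family also had summits more often than other genes, with 10 of 21 members (47.6%, odds ratio 3.22, p = 0.0137, adjusted p = 0.0335, two-sided Fisher's exact test). The mean over replicates was 53.6% ± 4.56 (SD, n = 4), and the odds ratio was 6.07 with summits in the gene body or 2 kb upstream and 9.29 with summits given to the nearest TSS. Of these genes 10 were also in the ecdysone list, 6 of them with a summit. Members outside the ecdysone list with a summit were Hr96, a xenobiotic and lipid sensor gene (rank 678), Hnf4 (977), ERR (2004) and eg (5242). The ERR summit, at 3L 8186893, lay 222 bp upstream of ERR and 36 bp downstream of the start of Atg18a on the opposite strand, and was counted for both. Hr51, Hr83, dsf, kni, knrl, svp and tll had no summit within 1 kb of a TSS. Inside the gene knrl held 4 summits and svp 2, counts likewise not compared with gene length. Under the 1 kb rule matched lists averaged 41.1%, from which the list did not differ past the threshold (ratio 1.16, adjusted p = 0.810, permutation test). No matched lists were run under the gene-body and nearest-TSS rules. Its call was lost in the 4141 peaks with the highest signal (adjusted p = 0.134) and among peaks met by all 4 replicates (adjusted p = 0.0792, Fisher's exact test in both).

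The 10 strongest peaks recurred at the top of every replicate, where none ranked below 18. Of their summits 7 lay within 1 kb of a protein-coding TSS and 9 were upstream of the nearest one. The strongest (signal 4313; 3L from 19590386 to 19590856) lay 86 bp upstream of CG14100, in intergenic sequence, with a mean replicate rank of 2.00 ± 1.41 (SD, n = 4). The next (2L from 480558 to 481408; signal 4276) lay in an intron of ush, 1365 bp upstream of the TSS of cbt, a zinc finger gene inside ush. Then came Ugalt (X, summit at 2703891, 39 bp upstream; signal 4040), CG11050 (2L, summit at 6612707 in an intron, 1020 bp downstream; 3868) and the intronic Eip78C peak, whose nearest TSS belongs to the nested gene CG43218. The others were at Lk6 (signal 3461), a kinase gene, larp (3381), PNPase (3366), CenG1A (3316) and CG7601 (3232).

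In the optimal set, ribosomal protein genes had the highest share of members with a summit, although ecdysone response genes had a higher share in replicate 1 (80% against 76.1%) and circadian genes the highest in replicate 2 (66.7%, against 60% of ecdysone response and 59.8% of ribosomal protein genes). Of 92 cytoplasmic ribosomal protein genes 64 (69.6%) had a summit within 1 kb of a TSS (odds ratio 8.24, p = 2.11e-22, adjusted p = 4.65e-21, two-sided Fisher's exact test), with a mean of 70.9% ± 8.30 (SD, n = 4) over replicates. This held against matched lists, which averaged 22.0% (ratio 3.16, raw p = 0.0002, the smallest possible, adjusted p = 0.0022, permutation test). Their peaks were also stronger, with a mean rank of 3013 for 73 peaks against 4152 for the other optimal peaks (p = 3e-05, adjusted p = 0.00042, permutation test). The strongest were at RpS19b (rank 250), RpS27 (332), RpL7 (450) and RpL32 (697). The RpS19b summit lay 899 bp upstream, in an intron of another gene, and the others lay 2 to 122 bp from a TSS. The list of heat shock and highly transcribed genes had 12 of 21 members with a summit (57.1%; odds ratio 4.73, p = 0.0005, adjusted p = 0.0022, Fisher's exact test), also above matched lists (ratio 2.30, adjusted p = 0.00587, permutation test). Its leading members were Hsp27 (rank 17, mean replicate rank 18.8 ± 3.59, SD, n = 4), Gapdh2 (48), Act5C (202) and Hsp26 (508). The list is mixed. Of its heat shock genes Hsp22, Hsp23, Hsp26, Hsp27, Hsp83 and Hsc70-4 had a summit within 1 kb of a TSS. Hsp67Bc, Hsp68 and the listed Hsp70 genes had none, and neither did Act42A, Gapdh1 and Polr2A.

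Metabolic and growth genes had summits at many promoters. Of 20 genes of fat body storage and lipid metabolism 12 (60.0%) had a summit (odds ratio 5.32, p = 0.000268, adjusted p = 0.00147, Fisher's exact test), and each replicate gave 55.0%. Lpin, a phosphatidate phosphatase gene (rank 49, mean replicate rank 52.8 ± 27.0, SD, n = 4), SREBP (717), the lipase gene bmm (1294) and Mtp (1517) led, whereas the genes of the larval serum proteins Lsp1alpha, Lsp1beta, Lsp1gamma and Lsp2, and also Fbp1 and Fbp2, had no summit within 1 kb of a TSS. Insulin and growth genes (9 of 17; odds ratio 3.99, raw p = 0.00515, adjusted p = 0.0162, Fisher's exact test) included sNPF (rank 1149), InR (2300) and foxo (3338). Circadian genes (7 of 12; odds ratio 4.96, raw p = 0.00689, adjusted p = 0.0189, Fisher's exact test) included sgg (rank 146), cry (1520), vri (3590) and dco (4805). Genes of disc eversion and matrix (9 of 20; odds ratio 2.90, raw p = 0.0256, adjusted p = 0.0511, Fisher's exact test) fell just short of the threshold and passed with summits given to the nearest TSS (odds ratio 2.90, adjusted p = 0.0388, Fisher's exact test), but not among peaks met by all 4 replicates. Its strongest peaks were at puc (rank 644), sqh (1245), Timp (1748) and Pvr (2717). Against matched lists the fat body, insulin, circadian and disc lists did not pass, with adjusted p of 0.153, 0.257, 0.310 and 0.951 (permutation test). The insulin and circadian lists also lost their calls among peaks met by all 4 replicates (adjusted p = 0.199 for each, Fisher's exact test). Neither passed in each replicate's own list. The insulin odds ratio averaged 2.58 over replicates other than 3 and was 2.53 among peaks met by all 4. Its call also ended in the 4141 peaks with the highest signal (adjusted p = 0.0628, Fisher's exact test). The circadian odds ratio averaged 2.63 over replicates other than 2 and was 2.13 in those 4141 peaks (adjusted p = 0.315, Fisher's exact test).

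**Figure D2:**
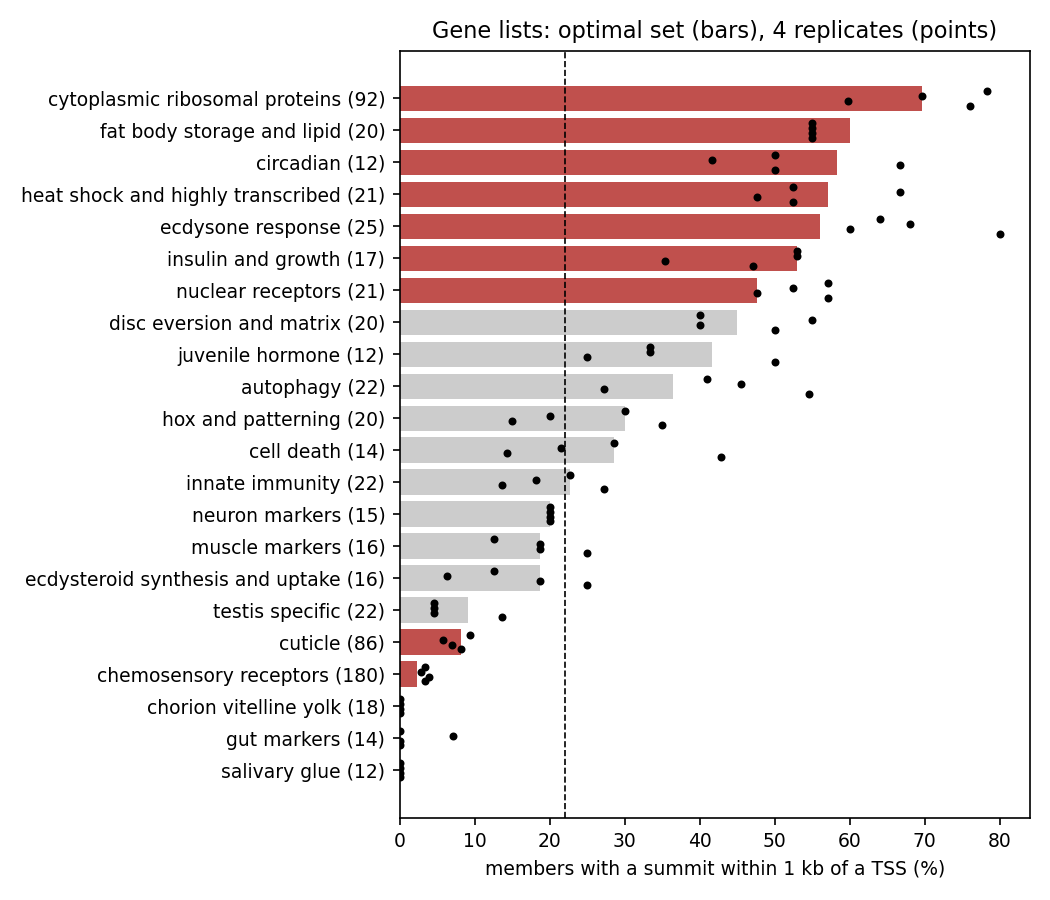
Share of the members of each gene list with a summit within 1 kb of a TSS (horizontal axis, %); bars are the optimal set, points the 4 replicates' 8282 strongest peaks, the dashed line all protein-coding genes (22.0%), and numbers in brackets the members. Red bars passed the adjusted threshold of 0.05; ribosomal protein genes stand highest at 69.6% and chemosensory receptor genes at 2.22%.

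Chemosensory receptor genes rarely had a summit. Among 180 chemosensory receptor genes only Ir94h (rank 1865), Or88a (4979), Or9a (5648) and Ir94f (6926) had a summit (2.22%; odds ratio 0.0792, p = 1.24e-14, adjusted p = 1.36e-13, two-sided Fisher's exact test), which was also below matched lists (ratio 0.132, adjusted p = 0.0022, permutation test). The odds ratio ranged from 0.0248 within 500 bp of a TSS to 0.298 with summits given to the nearest TSS. Of 86 cuticle genes 7 had a summit (8.14%; odds ratio 0.312, raw p = 0.000964, adjusted p = 0.00353, Fisher's exact test), led by Cpr72Eb (rank 711) and Cpr62Ba (2820), then Cpr47Ed (3702) and Cpr47Ec (4703). The cuticle deficit was stronger within 500 bp of a TSS and was no longer called with summits given to the nearest TSS (odds ratio 0.561, adjusted p = 0.0801, Fisher's exact test). None of 18 chorion, vitelline and yolk genes had a summit within 1 kb (raw p = 0.0196, adjusted p = 0.0431, Fisher's exact test), where a count of 0 allows up to 16.7%. The cuticle and chorion lists both lay below matched lists, which averaged 14.2% and 13.3%, without passing the threshold (adjusted p = 0.309 and 0.310, permutation test), and both lost their calls among peaks met by all 4 replicates (adjusted p = 0.0886 for cuticle genes, Fisher's exact test). None of 12 salivary glue genes, which are expressed before puparium formation, had a summit (adjusted p = 0.137; up to 25% allowed), nor did any of 14 gut marker genes (adjusted p = 0.0922; up to 21.4% allowed), both short of the threshold of the exact test. With summits in the gene body or 2 kb upstream the glue list still had none and passed (adjusted p = 0.0474, Fisher's exact test).

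The other 9 lists did not pass the test, with adjusted p between 0.190 and 1 in Fisher's exact test. Single members nevertheless had strong peaks. Among cell death genes hid, which triggers apoptosis of larval tissues, had a peak of rank 183 (mean replicate rank 209 ± 67.4, SD, n = 4; summit at 3L 18185930, 289 bp upstream), and Diap1, the inhibitor of apoptosis, one of rank 385 (396 ± 68.4, n = 4). Drice (5470) and Dcp-1 (8068) followed, and 4 of 14 members had a summit in all. Autophagy genes (8 of 22) were led by Atg2 (1266), Atg17 (1374), Atg18a (2004) and Atg8a (2774). Juvenile hormone genes (5 of 12) were led by Hmgs (2173), gce (2429) and Jheh1 (2453). Of ecdysteroid synthesis and uptake genes (3 of 16), Oatp74D, the ecdysone importer gene, ranked 2999, shd 7263 and mld 7974. Neuron markers (3 of 15) were led by elav (248), then Syx1A (2696) and futsch (5990), and muscle markers (3 of 16) by sls (1470), Tm1 (3122) and Mef2 (8189). Innate immunity genes (5 of 22) included dl (1307), Tl (1632), spz (6482) and PGRP-LC (6748), and testis genes (2 of 22) can (4423) and Mst87F (8102). Patterning genes (6 of 20) passed when summits were counted in the gene body or 2 kb upstream (odds ratio 2.96, adjusted p = 0.0474) or given to the nearest TSS (odds ratio 11.6, adjusted p = 3.12e-06, Fisher's exact test in both). Both rules reach further at genes that are long or far from others, and no matched lists were run under them. Under the 1 kb rule the share lay below that of matched lists without passing (ratio 0.721, adjusted p = 0.590, permutation test). Within 1 kb of a TSS patterning genes had weak peaks, at dac (5358), Dll (6441), Antp (6553) and sd (7948). Their 6 peaks had a mean rank of 7068 against 4139 for the other optimal peaks (p = 0.00126, adjusted p = 0.00882, permutation test). Of the 14 lists with at least 5 peaks only this list and the ribosomal list passed that test, and within the 4141 peaks with the highest signal the ribosomal call ended (mean rank difference -196, adjusted p = 0.652, permutation test), while the patterning list had no peaks there to test.

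Peaks gathered in front of genes and avoided coding sequence. Of the 8282 summits 3467 (41.9%, 95% exact interval 40.8 to 42.9) lay within 1 kb of a TSS, where 23.6% of bases do (ratio 1.78, p = 3.9e-295, two-sided exact binomial test). Replicates gave 45.0% ± 3.18 (SD, n = 4). The weaker 21718 peaks of the pooled list gave 30.7%, a smaller share than the optimal set (odds ratio 1.62, p = 4.86e-73, Fisher's exact test). Relative to the nearest protein-coding TSS 1113 summits lay within 200 bp upstream and 350 within 200 bp downstream. Introns outside promoters held 39.7% of summits, close to their 36.2% of bases, and intergenic sequence 16.9% against 25.2% (adjusted p = 3.63e-11 and 1.4e-73, exact binomial test). Coding exons outside promoters held only 10 summits (0.121%), where 9.91% of bases lie. With promoters included, 27 summits (0.326%) were in coding sequence, which makes up 16.0% of bases. The 3′ UTRs held 0.676% against 4.23% (ratio 0.160, adjusted p = 7.27e-87, exact binomial test; ratio 0.0858 in the 4141 peaks with the highest signal) and 5′ UTRs 0.169% against 0.449% (ratio 0.376, adjusted p = 2.79e-05, exact binomial test; ratio 0.696 with promoters of 500 bp). The intron excess did not pass the threshold in every replicate's own list (ratio 1.02 to 1.05 over sets of 3 replicates), and against the weaker pooled peaks introns were under-represented (odds ratio 0.890).

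**Figure D3:**
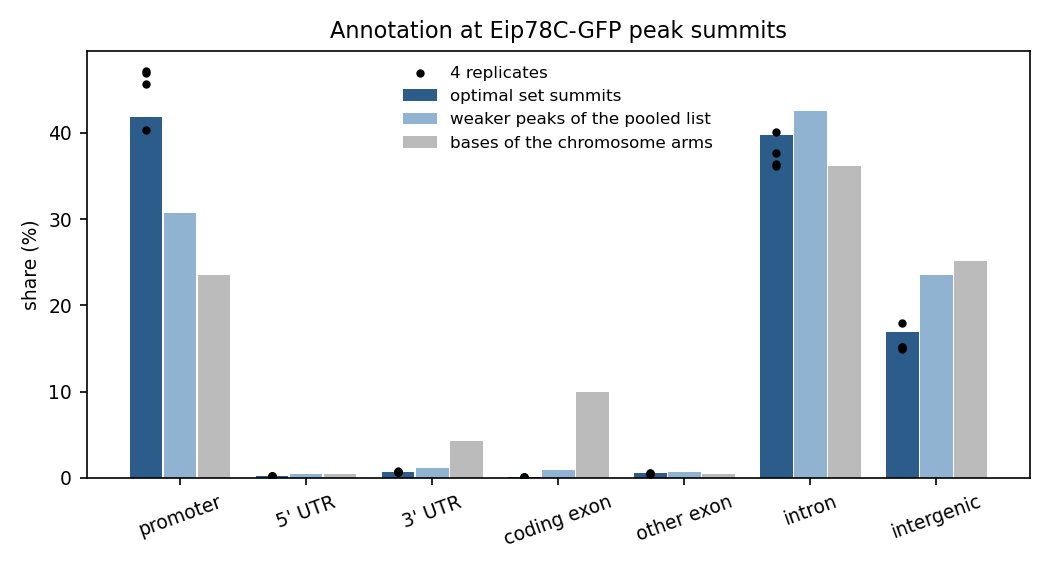
Share of summits (vertical axis, %) in each annotation class for the optimal set and the weaker peaks of the pooled list, beside the share of bases; points are the 4 replicates' 8282 strongest peaks. Promoters hold 41.9% of optimal summits against 23.6% of bases, and coding exons 0.121% against 9.91%.

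The summits were rich in A and T. Within 100 bp centred on optimal summits the G+C content averaged 33.4%, against 43.3% at 500 bp to the right and 42.1% over the arms. The replicates' strongest peaks averaged 34.1% ± 0.416 (SD, n = 4) at the summit and 43.3% ± 0.128 at 500 bp. The weaker pooled peaks dipped less, to 39.2%.

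**Figure D4:**
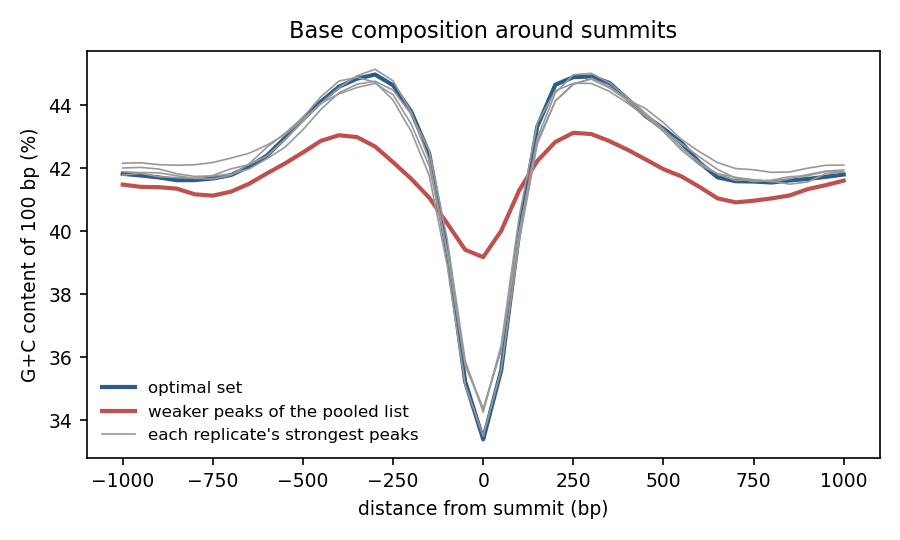
Mean G+C content of 100 bp (vertical axis, %) against distance from the summit (bp). The optimal set and each replicate's strongest peaks fall to 33.4% and on average 34.1% at the summit, and the weaker pooled peaks to 39.2%.

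Peaks were spread over all large arms, with modest differences. Arm X had 67.0 peaks per Mb (ratio to its share of bases 1.11) and 3L 66.3 (ratio 1.10), both above expectation (adjusted p = 7.65e-06 for each, exact binomial test). Arm 2R was lower, at 55.6 per Mb (ratio 0.924, adjusted p = 0.0014, exact binomial test), a call that ended among peaks met by all 4 replicates (adjusted p = 0.0517) and in the 4141 peaks with the highest signal (adjusted p = 0.107, exact binomial test). The small arm 4 had 24 peaks, 17.8 per Mb (ratio 0.296, adjusted p = 5.26e-13, exact binomial test), and among peaks met by all 4 replicates its ratio was 0.161. No optimal peak lay on Y (a count of 0 allows up to 0.0362% of the set), and neither did any peak of the whole lists, so binding on Y could not be assessed. The expected shares count the bases of Y, which raises the ratio of every other arm. The density on X was 1.09 times that of the large autosomal arms (95% exact interval 1.03 to 1.16). In the weaker pooled peaks it was 1.21 times (1.17 to 1.25), so the excess on X was not particular to the optimal set. In the replicates' own strongest peaks the excess on X did not pass the threshold in each, with the ratio to the autosomal arms between 0.987 in replicate 2 and 1.13 in replicate 4.

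Binding motifs of nuclear receptors were not enriched under the summits. The half-site AGGTCA occurred in 334 of 8282 windows of 200 bp at the summit and in 365 windows 500 bp away (ratio 0.915, adjusted p = 0.354, two-sided exact McNemar test). In the replicates' own lists the site was less common at the summit, past the threshold in each (ratio 0.821 ± 0.0151, SD, n = 4; largest adjusted p = 0.0319, exact McNemar test), and scrambled versions had a median ratio of 0.868 in the optimal set. With the control window 1000 bp away the optimal set also passed (ratio 0.825, adjusted p = 0.0159, exact McNemar test). The extended monomer site preferred by Rev-erb type receptors occurred in 44 and 49 windows (ratio 0.898, adjusted p = 0.900, exact McNemar test). Its direction turned with the control window to the left (ratio 1.10) or 1000 bp to the right (ratio 1.69, adjusted p = 0.0736, exact McNemar test). The direct repeats with 2 and 1 spacer bases occurred in 0 and 1 windows each, and the inverted repeat of the ecdysone receptor in 5 and 5. With the control window to the left the repeat with 1 spacer base was less common at the summit (ratio 0, adjusted p = 0.025, exact McNemar test). In the replicates' own lists the ratio of the inverted repeat was 0.440 ± 0.129 (SD, n = 4), without a call. The FTZ-F1 site was less common at the summit (30 against 71 windows, ratio 0.423, adjusted p = 0.000123, exact McNemar test), but no more so than its scrambled versions allowed, since 9 of 100 had a ratio as low, and its call ended over 1 kb from a TSS (ratio 0.545, adjusted p = 0.112, exact McNemar test).

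DRE, motif 1 and the core site of Su(Hw) were more common at the summit, whereas the BEAF site was not (9 against 7 windows, adjusted p = 0.989, exact McNemar test). DRE, the site of the promoter factor DREF, occurred in 123 windows at the summit and 32 beside it (ratio 3.84, adjusted p = 2.97e-13, exact McNemar test; replicates 3.83 ± 0.561, SD, n = 4), a ratio above all 100 of its scrambled versions, whose median was 1.67 (p = 0.0198, permutation over scrambles, the smallest possible). Counted at the summit alone, DRE was 1.63 times as common as the median of its scrambled versions, which did not pass the test (unadjusted p = 0.238, permutation over scrambles). With the control window to the left the ratio was 2.37. At summits over 1 kb from a TSS its ratio of 2.13 did not pass the test (adjusted p = 0.192, exact McNemar test). Motif 1, the core promoter element bound by M1BP, occurred in 66 and 22 windows (ratio 3.00, adjusted p = 1.15e-05, exact McNemar test), with ratios of 2.06 to 2.97 in the 4 replicates, and 6 of 97 scrambled versions had a ratio at least as high. At the summit alone it was 14.7 times as common as the median of its scrambled versions (unadjusted p = 0.0396, permutation over scrambles). The ratio was 4.71 with the control window to the left and 7.60 in windows of 100 bp. Its call ended among peaks met by all 4 replicates (ratio 1.53, adjusted p = 0.323) and in the 4141 peaks with the highest signal (ratio 1.54, adjusted p = 0.448, exact McNemar test in both). The core site of the insulator protein Su(Hw) had a ratio of 2.64 (74 against 28 windows, adjusted p = 1.5e-05, exact McNemar test), and 1.77 among peaks met by all 4 replicates, where the call ended (adjusted p = 0.0709, exact McNemar test). It also ended in the 4141 peaks with the highest signal (adjusted p = 0.0551, exact McNemar test). In the replicates' own lists the site fell short only in replicate 3 (ratio 1.5, adjusted p = 0.109, exact McNemar test). Of 100 scrambled versions 18 had a ratio at least as high as 2.64. At the summit alone the Su(Hw) site was 4.48 times as common as the median of its scrambled versions (unadjusted p = 0.0396, permutation over scrambles). GATA (ratio 1.35, adjusted p = 1.83e-27) and Forkhead (1.23, adjusted p = 1.29e-06, exact McNemar test in both) sites were more common too, but 76 and 71 of 100 scrambled versions had ratios at least as high. GAGA (0.758, adjusted p = 0.000402) and the E-box (0.704, adjusted p = 0.00301, exact McNemar test in both) were less common, likewise within the range of scrambled versions. The GAGA ratio was 0.483 over 1 kb from a TSS and the E-box ratio 0.448 in windows of 100 bp. With the control window 1000 bp away neither passed (adjusted p = 0.744 and 0.0905, exact McNemar test). Nor did GAGA pass in each replicate, where its ratio reached 1.03 in replicate 3. The E-box call ended in the 4141 peaks with the highest signal (adjusted p = 0.0649, exact McNemar test). In the replicates' own lists the E-box fell short only in replicate 3 (ratio 0.799, adjusted p = 0.0766, exact McNemar test).

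**Figure D5:**
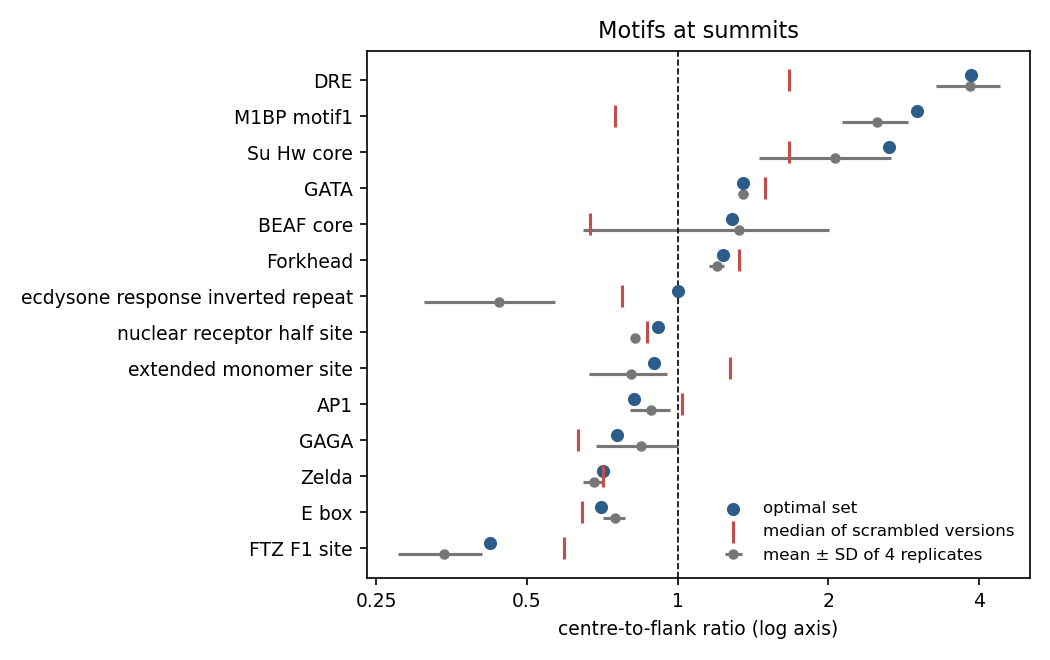
Ratio of windows with each motif at the summit to windows 500 bp to its right (log horizontal axis), for the optimal set, the mean ± SD of 4 replicates and the median of the motif's scrambled versions; motifs with a ratio of 0 are left out. DRE at 3.84 and motif 1 at 3.00 lie furthest right, and the nuclear receptor half-site lies at 0.915.

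The same libraries were also deposited on the older build dm3, and counts on the builds were close. The dm3 optimal set held 8393 peaks, 111 more than the dm6 set. X carried 1616 of them, against 1578 on dm6, and 3L 1897 against 1863. The dm3 lists also cover unplaced, heterochromatic and mitochondrial sequences, where the optimal set had 3 peaks. There the replicate lists had 28, 184, 25 and 57 peaks in replicates 1 to 4.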

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

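In this part the tissue-list test and the test of promoter class as the whole cause were chosen only after the values were seen, and the others before. Dixon's test was applied to 58 quantities measured in the 4 replicates, and 9 had a replicate far from the others, where chance gives about 1 in 20, or 2.90. That chance value is only a rough guide, because several quantities overlap and small gene counts tie. Replicate 2 accounted for 5 of them. Its whole list of 30000 peaks met 95.8% of the optimal set, against 99.1% to 99.7% in the others. That list had 4394 peaks on X, against 5762 to 6016, and 7616 on 3R, against 6878 to 6975. Among its 8282 strongest peaks 2021 were on 3R, against 1941 to 1946, and 17.9% of summits were intergenic, against at most 15.2%. Below rank 8282 its density on X was 0.732 times that of the large autosomal arms, and 1.14 to 1.19 times in the other replicates. Replicate 1 stood apart in the share of summits in 3′ UTRs (0.773%, where the lowest was 0.688%) and of testis genes with a summit (13.6% against 4.55% in each other replicate). Replicate 3 was the only one with a summit at a gut marker gene (7.14% of members), and replicate 4 had the lowest centre-to-flank ratio of GATA sites (1.31 against 1.36 to 1.37). The causes were not tested.

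Peaks at the lists of ribosomal protein genes, of heat shock and highly transcribed genes, and of ecdysone response genes could come from something other than binding by the receptor. Chromatin of active genes is often recovered in immunoprecipitations, and no untagged control was among the samples analysed. Strong transcription in whatever tissue stays open: 7.14% of muscle, gut and salivary glue genes had a summit (3 of 42), but no expression was measured, so whether these genes were transcribed is not known. A promoter type shared by genes active in most cells may contribute. Among genes in no list, those with DRE or motif 1 near a TSS had a summit in 26.9% of cases, against 20.9% of others (odds ratio 1.40, 95% interval 1.25 to 1.56), but 26.9% is far below the 69.6% of ribosomal protein genes (exact interval 59.1 to 78.7). DRE and motif 1 were not counted at the ribosomal protein genes themselves. The comparison therefore cannot decide whether the promoter type of those genes accounts for their peaks. Gene length and number of TSSs did not account for the ribosomal protein list (adjusted p = 0.0022) and could account for the ecdysone response list (adjusted p = 0.685, permutation test in both), whose peaks are therefore not shown to be specific to it. Whether the ribosomal peaks come from the tagged receptor or from open chromatin of active promoters was not tested and stays open.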

How the results depend on the processing

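The background of weaker pooled peaks and the ranks of named peaks without each replicate were chosen after seeing the data; all other alternatives were planned. Depth limits these results in a way that could not be measured, since the lists hold no read counts. The promoter excess kept its direction and call under each of 9 alternatives, with shares of 31.3% (500 bp) to 55.3% (2 kb), and an odds ratio of 1.62 against weaker pooled peaks. Leaving out each replicate gave 44.3% to 46.6%. The 6 annotation classes and 5 arms past the threshold numbered 5 to 7 and 4 to 6 under the alternatives. The arms counted include Y, where no list had a peak, so that call was fixed in advance and says nothing about binding.

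Counts of peaks and shares moved with the rule. The stricter set has 4141 peaks by construction. Mean replicate support was 63.3% with overlap of at least 50% of both intervals, 78.4% with summits within 100 bp, 50.2% with fewer peaks per replicate (by construction) and 98.5% with whole lists. Pairwise agreement was 66.1%, 68.9%, 79.9% and 66.5% in the same order. Without each replicate in turn support was 83.1% to 84.1% and agreement 76.3% to 78.4%. Of 22 gene lists 10 passed the threshold, and 6 in the stricter set, 5 among peaks in all 4 replicates, 3 against matched lists, 9 to 11 under other gene assignments and 8 without any one replicate. Lists passing the strength test fell from 2 to 0 in the stricter set, where only 8 lists had enough peaks, patterning not among them. That set is chosen by signal, which narrows rank differences by construction. Motifs past the threshold numbered 8, with 5 in the stricter set, 2 against scrambled versions in the same windows, motif 1 and Su(Hw) but not DRE (unadjusted p, because 100 scrambles cannot pass an adjusted threshold for 16 motifs), 6 to 10 with other windows or peaks and 6 to 8 without each replicate. The cause was not tested.

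Directions turned mostly where no call had been made; introns had been called. Against weaker pooled peaks introns (0.890) and other exons (0.779) turned below 1, and with bases near TSSs as denominator so did arms 2L (0.927, past the threshold with an adjusted p of 0.00132) and 3R (0.998, adjusted p = 0.917, exact binomial test in both). For gene lists the odds ratio of patterning genes was 0 in the stricter set and among peaks in all 4 replicates and 0.865 to 1.18 without each replicate, the lowest without replicate 1, and the ratio of its share to that of matched lists was 0.721. It rose past the threshold to 2.96 with gene bodies (adjusted p = 0.0474) and 11.6 with nearest-TSS assignment (adjusted p = 3.12e-06, Fisher's exact test in both). No matched lists were run under those rules, which reach further at genes that are long or far from others. Innate immunity turned to 0.638 in the stricter set, 0.605 among peaks in all 4 replicates and 0.691 to 0.866 without each replicate, and cell death to 0.850 without replicate 1 (up to 1.39 without another). Muscle markers turned to 1.04 (500 bp) and 1.31 (nearest TSS), neuron markers to 1.51 (all 4 replicates), 1.21 (gene body) and 1.93 (nearest TSS), and gut markers to 1.61 (nearest TSS). Rank differences in the stricter set turned to 258 for ecdysone response, 249 for autophagy, 104 for disc genes and 266 for fat body genes, and to 38.6 for the latter at 500 bp. Among motifs the extended monomer site turned to 1.10 (left flank) and 1.69 (1000 bp to the right), and the inverted repeat to 3.00 over 1 kb from a TSS. The ratio to scrambled versions at the summit is another quantity than the ratio to the flank, so lying on the other side of 1 is not a turned direction: it was 1.76 for the extended monomer site, 5.00 for the inverted repeat, 2.63 for GAGA and 0.839 for GATA. BEAF turned to 0.6 (stricter set), 0.4 (all 4 replicates), 0.692 (left flank) and 0.333 (over 1 kb from a TSS). The cause was not tested.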

Other observations

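In this part the 8-mer search and the test of the other peaks inside Eip78C were chosen only after the data were seen. A summit lay within 1 kb of a TSS for 63 of 290 tRNA genes (21.7%), a share close to that of protein-coding genes (22.0%), for 43 of 269 small nucleolar RNA genes (16.0%) and for 562 of 3289 other non-coding RNA genes (17.1%). Only 17 of 330 pseudogenes (5.15%) and 2 of 32 small nuclear RNA genes (6.25%) had one, and none of 99 rRNA genes (a count of 0 allows up to 3.03%). These shares were not tested.

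The strongest peak inside Eip78C raises the hypothesis that the receptor binds its own gene. Tagged flies may carry an extra copy of the locus, which would raise its reads. With the signal divided by 2 the peak would still rank 51 of 8282. This argues against an extra copy as the whole cause only if the score is proportional to reads and a factor of 2 covers the copy. The other 10 peaks inside the gene had a median rank of 5331, in the weaker part of the set, with a best rank of 775. Strength was therefore not shared by every peak of the gene. These ranks cannot weigh against an extra copy, because weak peaks that it raised could still be weak. The score of the strongest peak was 5.93 times that of the next one in the gene, on a scale that is not stated. Open chromatin at this intron remains possible, because no untagged control was analysed, so binding by the receptor is a hypothesis only.

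A family of short sequences was enriched under the summits, whereas the motifs of nuclear receptors were not. On arms 2L, 3L and X (4909 peaks) every 8-mer with at least 3 G or C bases was compared between the 200 bp at the summit and the windows 500 bp to either side, and the 10 with the largest excess were kept. This search was made after seeing the data, and the sequences were then tested on arms 2R, 3R and 4, which had not been searched. CACTGAGA led, in 225 windows at the summit and 21 and 29 beside it. Most of the 10 shared the core CAGTG or its complement, among them TACACTGA, TCAGTGCA, CAGTGCAC and CACAGTGG. On the held-out arms CACTGAGA occurred in 156 of 3373 windows at the summit and 19 beside it (ratio 8.21, adjusted p = 2.27e-27, exact McNemar test). At least 1 of the 10 lay in 19.4% of held-out summits and 5.66% of flanks (ratio 3.42, p = 4.61e-65, exact McNemar test). The ratio over the replicates' strongest peaks was 3.20 ± 0.218 (SD, n = 4).

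The AT-rich composition of summits is argued against as the cause of this excess, since 100 scrambled sets of the same 8-mers reached ratios of 0.450 to 1.27, below the 3.42 observed. Copies of 1 repeated element are argued against too, because only 0.306% of 653 occurrences shared their surrounding 31 bp with another (5 mismatches or fewer). Promoter sequence in general does not account for it, as the ratio at held-out summits over 1 kb from a TSS was 4.33, above the 2.40 at those within 1 kb. Peaks with an 8-mer were stronger, by a mean rank difference of -355 (3842 with and 4197 without, p = 0.00072, permutation test). The excess was weaker at the pooled peaks below the threshold (ratio 2.14). These values raise the hypothesis of a sequence-specific DNA-binding protein at a part of these sites, which was not tested. Whether such a protein would be Eip78C or another one present at the same sites was not tested either. The strongest Eip78C summit held none of the 10.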
